A study of Homo sapiens with 3 samples.

How the data were processed

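Total RNA of OCUBM cells was labelled with biotin and hybridised to Affymetrix HG-U133 Plus 2 arrays, per the labels and the file headers. The 3 arrays were 1 of control cells and 2 of cells transfected with 12G FEZL, and groups and replicate numbers were taken from the sample titles. The deposited values are signal intensities on a linear scale, 1 per probe set and array, written by the Affymetrix software GCOS per the submitters' processing notes. Its version, its settings and any scaling target are not given in the sources used here. The authors' values had not been brought to 1 common level, since their 2% trimmed means differed by more than 5% between arrays. The files of scanner and fluidics settings, written per array, hold no measurement and were used only to learn how the arrays were handled. The 3 arrays share chip type, fluidics protocol and scanner, but were run on 2 fluidics modules and fall on 3 hybridisation days. Genomic positions were not used, since the array names no genome build.

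From the deposited intensities, quantile normalisation across the 3 arrays was followed by log2 with an offset of 16. The rule for normalising was fixed before the data were examined, as were the tests, the gene lists and the rule for named genes. The 62 Affymetrix control probe sets were kept out of the tests, and those of 1 control transcript are not reported here. Probe sets whose mean log2 value over the 3 arrays lay above the median of all others were tested. With 2 of the 3 arrays transfected, this filter lets dim probe sets in more readily where they rose than where they fell. Probe sets were named through GEO's platform annotation: 41091 had 1 gene symbol, 1801 had several and 11721 had none. Symbols were looked up by Entrez ID in RefSeq's gene table, which held 41037 of the 41091 and changed 0 of them. No gene was named from a probe set with several symbols, although such probe sets are given where they overlap a named gene. A gene was represented by its single-gene probe set with the highest mean log2 value.

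Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance on mean signal), with the group as the only term. Adjusted p values are Benjamini-Hochberg over the tested probe sets, with a threshold of 0.05. The 1 residual degree of freedom was supplemented by 7.53 prior degrees of freedom taken from all probe sets. The replicates are labelled biological, though no label says whether they came from separate cultures. The p values therefore rest on the spread between the 2 transfected arrays, moderated over all probe sets, and hold no spread of the control. Simulated data with 200 changed probe sets among 27306 were used to test the procedure. At 2-fold 0 of 50 simulated changes were found, at 4-fold 10 of 50, at 8-fold 41 of 50 and at 16-fold 49 of 50, with 5 false calls among 105. Changes under about 4-fold are therefore mostly not detectable with these arrays. The simulated arrays varied independently around 1 mean per probe set, with no technical difference between arrays. The real arrays differed in their control probe sets, so the share of false calls need not carry over to them.

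Of 34 gene lists, the 29 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 29. Beside it stand camera with a correlation estimated from the 1 residual degree of freedom, which called 0 lists, and the percentile of each list's median among 10000 random lists matched on mean signal. With the estimate, camera's p value rests on 1 degree of freedom, so these 0 calls cannot tell whether inter-gene correlation matters. For the MHC class I list the estimate was 0.011, near the preset value, yet the unadjusted camera p went from 3.5e-09 to 0.107. The rotation test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, called 0 of the 29 (lowest adjusted p = 0.583). It rests on the same 1 residual degree of freedom. The lists hold 791 symbols, of which 784 matched a gene. The genes named are those of the transfected gene, its paralog and 3 genes known from published work, the 12 genes with the largest rise and the 12 with the largest fall by the smaller of the 2 replicate differences, filled up from genes short of the threshold where fewer passed, and up to 4 members of each list described.

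Alternatives were another offset (1 or 64), no filter or a filter at the 75th percentile, the values as deposited, median centring, eBayes without the trend or robust, the mean of a gene's probe sets, a 3-fold rule, other list tests, and leaving out either transfected array. Choosing the brightest probe set on the control array, requiring a gene's other probe sets to agree, and list tests on gene means, on the other probe sets and with median centring were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.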

Results

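OCUBM is a human breast cancer cell line, and FEZL is an older name of FEZF2, a zinc finger transcription factor known for its part in specifying neurons of the forebrain. Transcript levels were measured on 3 Affymetrix arrays of 54675 probe sets each. The control group held 1 array, from cells given the transfection reagent Lipofectamine2000 and no expression vector. The 12G FEZL group held 2 arrays, from cells transfected with the 12G form of FEZL and labelled as biological replicates. The comparison asks which transcripts differed after 12G FEZL was introduced. Since the control cells received no vector, the comparison covers vector DNA and 12G FEZL together. The number of arrays limits the precision: 1 residual degree of freedom was left, the spread came from the 2 transfected arrays, and the lone control array was assumed to vary like them. Each array was hybridised on a day of its own, so hybridisation day and array cannot be told apart. The 2% trimmed mean of the deposited signal was 173.4 on the control array, 133.8 on 12G FEZL replicate 1 and 90.2 on 12G FEZL replicate 2, and the values were therefore quantile-normalised. All log2 differences below are 12G FEZL minus control on the log2(signal + 16) scale, which understates the change of dim probe sets, with the standard error from limma (n = 1 control array and 2 transfected arrays).

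The transcript of the transfected gene was far more abundant in the transfected cells. FEZF2 probe set 233897_at read a normalised signal of 1.63 on the control array and 5064.8 and 5279.9 on the transfected arrays, a log2 difference of 8.20 ± 0.35 (SE; limma, adjusted p = 0.000129). A further FEZF2 probe set, 233972_s_at, was higher by 4.76 ± 0.41 (SE; limma, adjusted p = 0.0140), with signals of 4.10 in control cells and 450.95 and 622.32 in transfected cells. The remaining FEZF2 probe set, 221086_s_at, stayed dim, at 9.13 in control cells and 6.30 and 6.67 in transfected cells. The trp control probe sets, which are expected to find no target in the sample, read between 1.4 and 10.9 as deposited on the control array. The FEZF2 probe sets were deposited there at 1.9 (233897_at), 4.8 (233972_s_at) and 11 (221086_s_at), the first 2 within that background range and the last just above it. Differences from a control signal in that range depend on the offset. The construct's sequence is not given in the sources used here, so which of these probe sets it can bind is not known. FEZF1, the paralog of FEZF2, had no single-gene probe set in the annotation table.

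Cytokine, chemokine and interferon-related genes were among the largest rises with 12G FEZL. CCL2, a chemokine that attracts monocytes, was higher by 4.04 ± 0.41 (SE), with signals of 14.6 on the control array and 575.1 and 413.8 on the transfected arrays. CXCL8 (interleukin 8), a chemokine that attracts neutrophils, was higher by 3.90 ± 0.38 (SE) with probe set 202859_x_at (limma, adjusted p = 0.0238). Its other probe set, 211506_s_at, gave 2.12 ± 0.45 (SE) and did not pass the threshold (limma, adjusted p = 0.0819). CXCL10, an interferon-induced chemokine, was higher by 4.15 ± 0.58 (SE), and IFIT3, an interferon-induced antiviral protein, by 3.67 ± 0.31 (SE). IFNL2, which encodes a type III interferon, was higher by 3.02 ± 0.39 (SE), from a signal of 30.5 to 350.95 and 373.03. A probe set that IFNL2 shares with other genes gave 1.09 ± 0.45 (SE). INHBA, a subunit of activin, was higher by 3.89 ± 0.50 (SE) with probe set 227140_at and by 3.87 ± 0.50 (SE) with a dimmer one, and its remaining probe set gave 0.83. On the control array these were deposited at 12.3, 5.1 and 11.2, in or just above the background range. TNF, tumour necrosis factor, gave 2.36 ± 0.47 (SE) with signals of 7.93 in control cells, also in the background range, and 152.9 and 72.9 in transfected cells, and did not pass the threshold (limma, adjusted p = 0.0677). SEMA5A, an axon guidance semaphorin, was dim on all 3 arrays and was not tested. Its probe sets gave -0.03, -0.28 and 0.72, the last of them 229427_at with signals of 1.63 in control cells and 11.2 and 14.8 in transfected cells. SEMA5A, TNF and CXCL8 were singled out beforehand from published work on FEZL, and are not independent evidence where that work chose them on these samples.

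**Figure D1:**
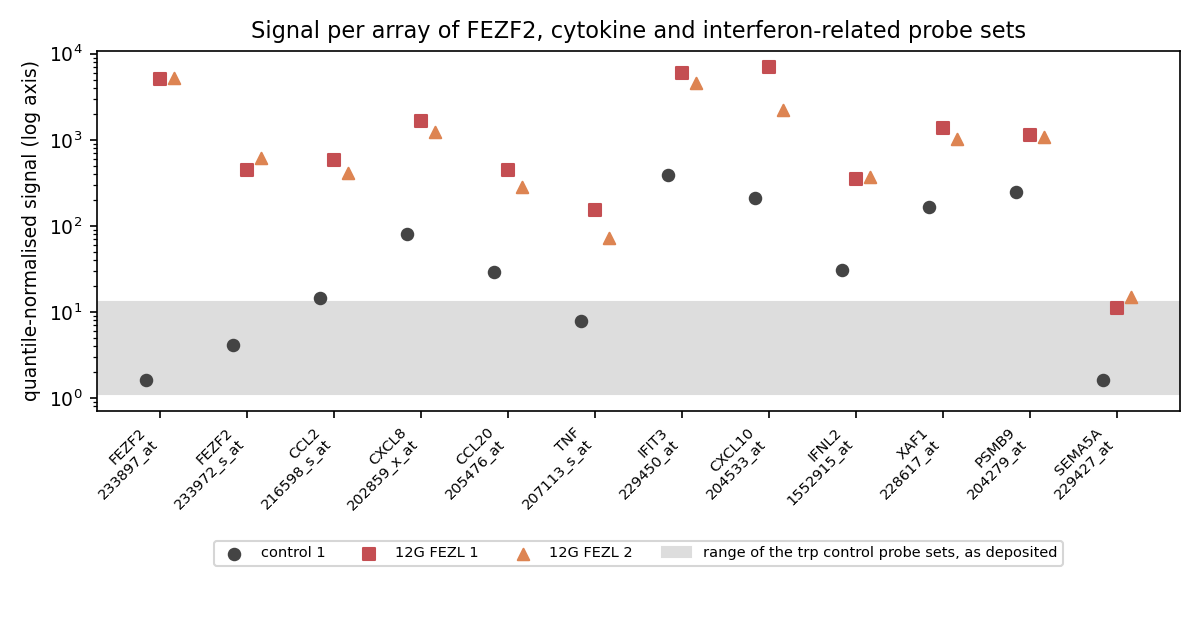
Quantile-normalised signal (log axis) of 12 probe sets, with 1 point per array: circles for control 1, squares for 12G FEZL 1 and triangles for 12G FEZL 2. The grey band is the range of the trp control probe sets as deposited over the 3 arrays (1.1 to 13.1). FEZF2 233897_at goes from 1.63 to 5064.8 and 5279.9, while SEMA5A 229427_at reads 1.63, 11.2 and 14.8.

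Among the gene lists, interferon response genes rose together (camera, adjusted p = 6.6e-23, or adjusted p = 0.778 with an estimated correlation). Here and below, p values with an estimated correlation rest on 1 degree of freedom and could hardly pass for any list. The median log2 difference of the interferon genes was 1.31, and 35 of the 39 tested members were higher than control in both transfected arrays. Here and below, both differences share the 1 control array, so their agreement is not independent. Of the 39, 7 passed the threshold over all probe sets tested and 25 passed when adjusted over the list alone, all 25 higher. The 7 included IFIT3, CXCL10, IFNL2 and XAF1, an interferon-inducible apoptosis factor that was higher by 2.72 ± 0.38 (SE). The other 2 tested probe sets of XAF1 had a median of 0.72. Genes of NF-kB signalling and inflammatory cytokines also rose (camera, adjusted p = 5.2e-13, or adjusted p = 0.778 with an estimated correlation), with a median of 1.40 over 22 members. Of these 22, 3 passed over all probe sets tested, namely CCL2, CXCL8 and CCL20, the last a chemokine that was higher by 3.05 ± 0.43 (SE). Adjusted over the list alone, 14 passed, all higher. MHC class I and antigen presentation genes rose (camera, adjusted p = 2.5e-08, or adjusted p = 0.778 with an estimated correlation), with a median of 0.88 over 14 members. PSMB9, a subunit of the immunoproteasome, was the 1 member past the threshold over all probe sets tested, at 2.08 ± 0.36 (SE), and 7 members passed when adjusted over the list alone. NLRC5, an activator of MHC class I genes, gave 2.24 ± 0.40 (SE), TAP1, a peptide transporter, 2.11 ± 0.44 (SE), and HLA-F 1.66 ± 0.34 (SE), none of these 3 past the threshold over all probe sets. The median of each of these 3 lists was above 0 in both transfected arrays. Their probe sets other than the brightest, a comparison added after seeing the data, had medians of 1.17 over 17 interferon genes, 0.80 over 9 NF-kB and cytokine genes and 1.11 over 8 MHC class I genes.

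**Figure D2:**
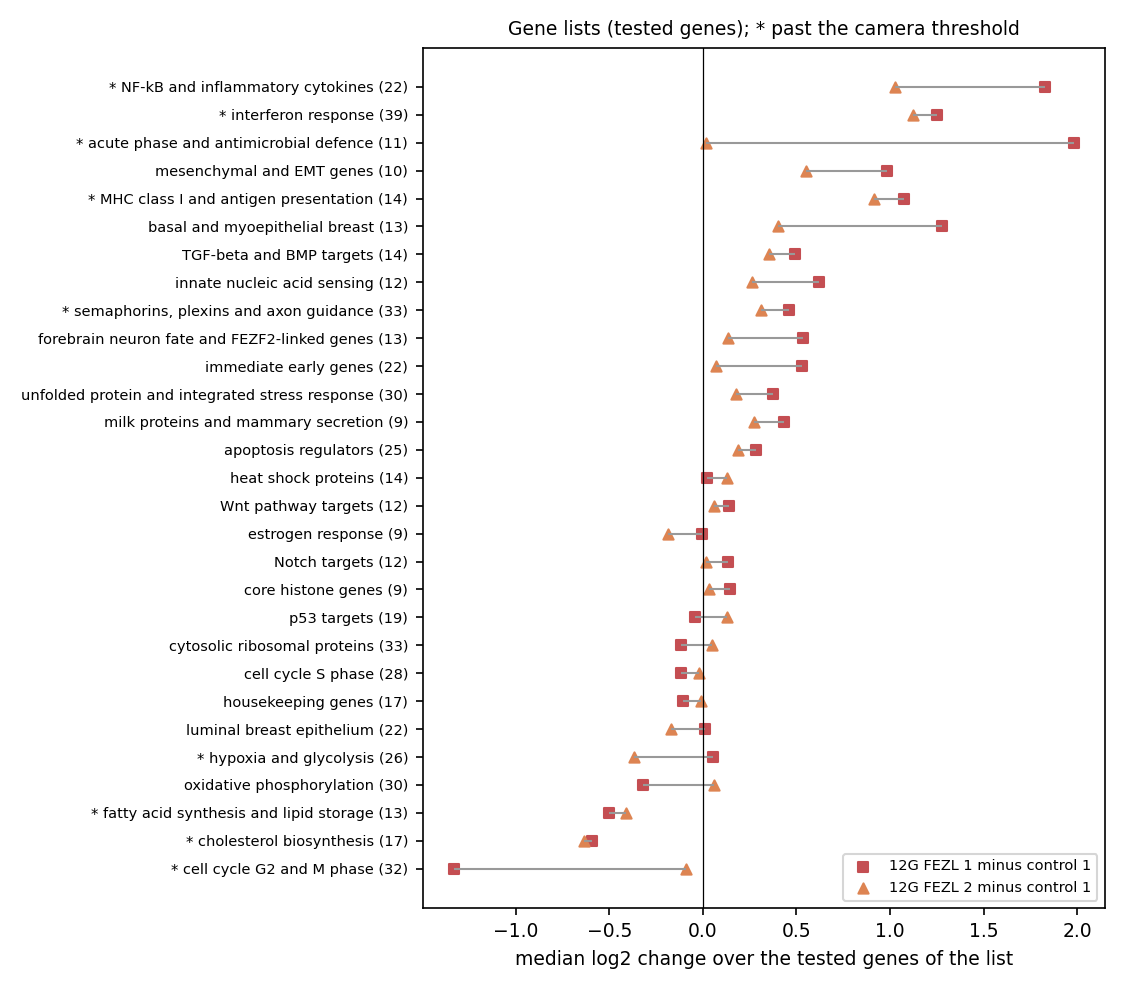
Median log2 difference from the control array over the tested genes of each of 29 gene lists, with squares for 12G FEZL 1, triangles for 12G FEZL 2 and a line joining them; the number of tested genes is in brackets and an asterisk marks an adjusted camera p under 0.05. The interferon list lies at 1.25 and 1.12, the cholesterol list at -0.60 and -0.64, and the G2 and M phase list at -1.33 and -0.09.

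Genes of sterol and fatty acid synthesis were lower as groups. The cholesterol biosynthesis list fell (camera, adjusted p = 5.6e-08, or adjusted p = 0.778 with an estimated correlation), with a median of -0.56 over 17 members. By their brightest probe sets none of its members passed over all probe sets tested, and 4 passed when adjusted over the list alone, all lower. These were IDI1 (-1.44 ± 0.33 SE), an isomerase of isoprenoid synthesis, SQLE (-1.40 ± 0.31 SE), which oxidises squalene, TM7SF2 (-1.77 ± 0.52 SE), a sterol reductase, and INSIG1 (-1.30 ± 0.34 SE), a sterol-sensing regulator. Dimmer probe sets of 2 members were called lower: 205822_s_at of HMGCS1 (-3.55 ± 0.38 SE; limma, adjusted p = 0.0238) and 213562_s_at of SQLE (-3.27 ± 0.39 SE; limma, adjusted p = 0.0266). For HMGCS1 the brightest probe set, 221750_at, gave only -0.41 ± 0.37 (SE). The list of fatty acid synthesis and lipid storage fell (camera, adjusted p = 0.000118, or adjusted p = 0.778 with an estimated correlation), with a median of -0.41 over 13 members and 2 members past the threshold when adjusted over the list alone. These 2 were THRSP (-2.69 ± 0.49 SE), a regulator of lipogenesis, and SCD (-1.56 ± 0.29 SE), the stearoyl-CoA desaturase, while fatty acid synthase, FASN, gave -1.08 ± 0.34 (SE) and its regulator SREBF1 gave -0.87 ± 0.39 (SE). Dimmer probe sets were called lower here too: 200831_s_at of SCD (-3.05 ± 0.38 SE; limma, adjusted p = 0.0266) and 229477_at of THRSP (-2.84 ± 0.44 SE; limma, adjusted p = 0.0368). In a comparison added after seeing the data, the probe sets other than the brightest had medians of -0.86 over 10 cholesterol genes and -0.80 over 11 fatty acid genes. Such probe sets had a median of -0.11 over all 6080 genes that have them. They lay about as low in some lists that camera did not call, at -0.97 for heat shock proteins, -0.73 for the unfolded protein response and -0.63 for S phase genes. The median of both lists was below 0 in each transfected array, the arrays on which the control transcripts' ratio of 3' to 5' signal was also higher (ACTB at 3.35 and 5.29, against 1.67 in control cells).

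The remaining lists past the threshold differed between the 2 transfected arrays or lay close to the other genes. G2 and M phase genes of the cell cycle fell as a group (camera, adjusted p = 8.0e-09, or adjusted p = 0.778 with an estimated correlation), with a median of -0.70 over 32 members. That median was -1.33 in replicate 1 and -0.09 in replicate 2, and without replicate 1 the list did not stand apart from random lists (adjusted p = 0.232). TOP2A, a DNA topoisomerase of dividing cells, gave -1.24 ± 0.39 (SE), and the kinase NEK2 gave -1.44 ± 0.53 (SE). By its brightest probe set no G2 and M phase member passed the threshold, over all probe sets or adjusted over the list alone, while the dimmer 211080_s_at of NEK2 was called lower (-2.56 ± 0.38 SE; limma, adjusted p = 0.0352). Acute phase and antimicrobial defence genes, 11 of 27 listed being tested, rose (camera, adjusted p = 0.0258, or adjusted p = 0.778 with an estimated correlation). Their medians were 1.98 in replicate 1 and 0.01 in replicate 2. Without replicate 1 the list's median lay below that of all tested genes and did not stand apart from random lists (adjusted p = 0.836). Their largest difference was that of SERPINA3, a protease inhibitor, at 3.40 ± 0.64 (SE), the 1 member past the threshold when adjusted over the list alone. Semaphorin, plexin and axon guidance genes rose slightly (camera, adjusted p = 0.0258, or adjusted p = 0.778 with an estimated correlation), with a median of 0.40 over 33 members, none past the threshold. Without replicate 1 they did not stand apart from random lists (adjusted p = 0.212). Their probe sets other than the brightest, a comparison added after seeing the data, had a median of -0.0070 over 18 genes and did not pass (camera, adjusted p = 0.488). EFNA1, an ephrin ligand, gave 1.62 ± 0.36 (SE), and SLIT2, a guidance cue, 1.82 ± 0.56 (SE). Hypoxia and glycolysis genes fell (camera, adjusted p = 0.0138, or adjusted p = 0.778 with an estimated correlation), with medians of 0.05 in replicate 1 and -0.37 in replicate 2 and no member past the threshold. They did not stand apart from random lists with both arrays (adjusted p = 0.104) or without replicate 2 (adjusted p = 0.860), and did without replicate 1 (adjusted p = 0.00116). Their other probe sets had a median of -0.30 over 12 genes and did not pass either (camera, adjusted p = 0.536). ANKRD37, a hypoxia-induced gene, gave -1.39 ± 0.36 (SE).

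Over all tested probe sets, 171 of 27306 passed an adjusted p of 0.05 in limma, 103 of them higher and 68 lower with 12G FEZL. With 1 probe set per gene, 55 of 12394 genes passed, 55 higher and 0 lower. That count depended on how a gene was represented. With the mean of a gene's probe sets 9 passed, and with the brightest on the control array, an alternative added after seeing the data, 33 passed, all higher. At an unadjusted p under 0.05 there were 1291 genes, 905 of them higher. The split between higher and lower rested on the scaling and, for probe sets, also on the offset. With offset 1 it was 97 higher and 32 lower probe sets, and with offset 64 it was 94 higher and 140 lower. It was 59 higher and 159 lower probe sets as deposited, and 244 higher and 747 lower with median centring. For genes it was 33 higher and 6 lower as deposited, and 104 higher and 66 lower with median centring. These scalings moved the median of all tested probe sets to -0.48 and -0.24, against 0.02 after quantile normalisation, and changes are relative to these shifts. Without a filter on dim probe sets, 0 of 54613 passed (5337 at an unadjusted p under 0.05), FEZF2 included, whose adjusted p was then 0.152. Among the named genes, IFNL2, CRIM1, CCL20, XAF1 and PSMB9 did not pass with the values as deposited. Counted without a test, 864 probe sets were at least 2-fold higher and 1073 at least 2-fold lower in both transfected arrays, which asks for 2 comparisons at once. For single pairs of arrays, replicate 1 against control gave 2079 higher and 2221 lower, and replicate 2 against control gave 1414 and 1735. Replicate 2 against replicate 1 gave 829 higher and 850 lower.

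By the smaller of the 2 replicate differences, the largest rises besides those of the genes already named belonged to VMP1, a protein of autophagosome formation (5.26 ± 0.56 SE), the small GTPase RIT1 (3.98 ± 0.60 SE), the transcription factor MGA (3.48 ± 0.45 SE), the ribosomal protein gene RPL27A (3.31 ± 0.39 SE) and CRIM1 (3.12 ± 0.40 SE). Their other probe sets often differed. Probe sets that VMP1 shares with other genes gave -0.45, 1.39 and 2.74, and the one that RPL27A shares gave -0.88. The other 4 probe sets of RIT1 ranged from 0.04 to 3.73, those of MGA from 0.13 to 0.92, and those of CRIM1 from 0.25 to 0.68. No gene's brightest probe set passed the threshold in the lower direction, so the 12 lowest by the same measure are given as values. Their log2 differences were -2.69 for THRSP, -2.17 for M6PR, a mannose 6-phosphate receptor, -2.19 for STT3A, a subunit of the oligosaccharyltransferase, -1.94 for the pseudogene NUS1P3, -1.79 for HBS1L, -1.72 for MTA2, -1.69 for GTF2I, -1.73 for the nucleoside transporter SLC29A1, -1.75 for OSGIN2, -1.95 for LPCAT3, -1.73 for DOP1B and -1.68 for LMBR1. Their standard errors ran from 0.35 to 0.49 and their limma adjusted p values from 0.0518 to 0.0970. With median centring each of the 12 passed as lower. Shared probe sets gave -0.76 for M6PR, -0.79 and -0.07 for GTF2I, and -2.56 for NUS1P3, the last called lower (limma, adjusted p = 0.0372). Other single-gene probe sets gave -2.84 and -1.53 for THRSP, -0.56 for SLC29A1 and -0.035 for LPCAT3. They ranged from -0.55 to -0.28 for OSGIN2, from -1.35 to 0.22 for HBS1L and from -1.52 to 0.06 for LMBR1. The rest had no other tested single-gene probe set.

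**Figure D3:**
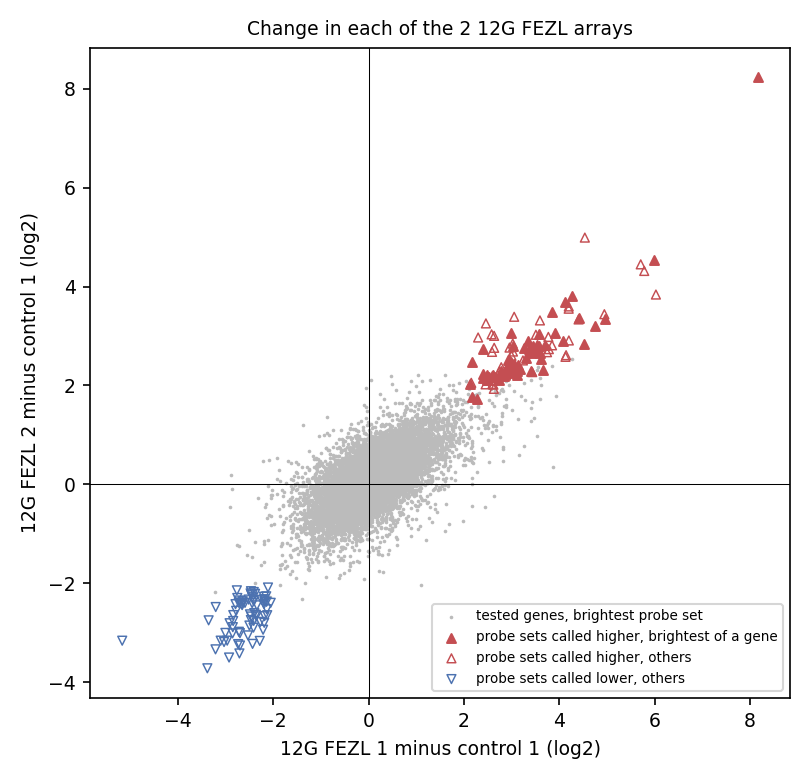
Log2 difference from the control array in 12G FEZL 1 (x axis) and 12G FEZL 2 (y axis). Grey points are the 12394 tested genes by their brightest probe set, and triangles are the 171 probe sets past the threshold, filled where the probe set is the brightest of its gene; all 68 lower ones are open.

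The 68 lower probe sets held no gene's brightest probe set. Of these 68, 58 named a single gene, and their median log2 difference was -2.54, while the brightest probe sets of the same genes had a median of -0.38. The lowest of them, chosen here after its values were seen, belonged to HMGCS1, an enzyme of cholesterol synthesis: 205822_s_at gave -3.55 ± 0.38 (SE) and the brighter 221750_at gave -0.41 ± 0.37 (SE). Of the 55 genes that rose, 36 had other tested probe sets. In 9 of these the others had a median rise of at least 1, in 25 the median lay within 1 of no change, and in 2 it was lower by at least 1. Over the 6080 genes with several tested probe sets, the other probe sets lay at least 1 below the brightest one's change in 15.2% of genes for replicate 1 and 13.8% for replicate 2, each against control, and in 4.14% between the 2 transfected arrays. The brightest probe set was chosen on the mean of all 3 arrays, 2 of them transfected. That choice favours probe sets that rose against control, so part of the excess over 4.14% may be built in.

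**Figure D4:**
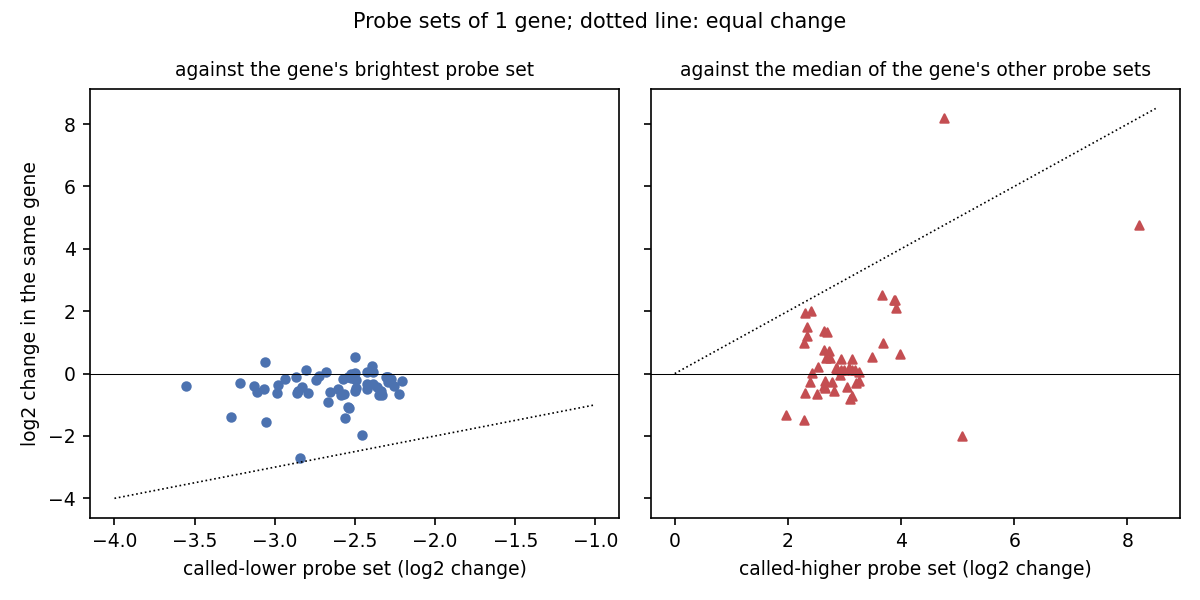
Left, the log2 difference of the 58 single-gene probe sets called lower (x axis) against that of the brightest probe set of the same gene (y axis). Right, single-gene probe sets called higher (x axis) against the median of the gene's other tested probe sets (y axis); the dotted lines mark equal change. On the left the brightest probe sets range from -2.69 to 0.52, with a median of -0.38.

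Control probe sets differed between the arrays as well. The signal at the 3' end over that at the 5' end was 0.97 for GAPDH and 1.67 for ACTB on the control array. On 12G FEZL replicate 1 these ratios were 1.33 and 3.35, and on replicate 2 they were 1.27 and 5.29. The dap transcript, added to the sample before labelling, had a ratio of 2.40 on the control array and 11.8 on replicate 1. The added poly-A transcripts had a median signal of 292.2 on the control array, 67.0 on replicate 1 and 1.30 on replicate 2, where they were at background. Of the deposited signals, 39.9% were below 16 on the control array, 41.7% on replicate 1 and 51.7% on replicate 2.

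**Figure D5:**
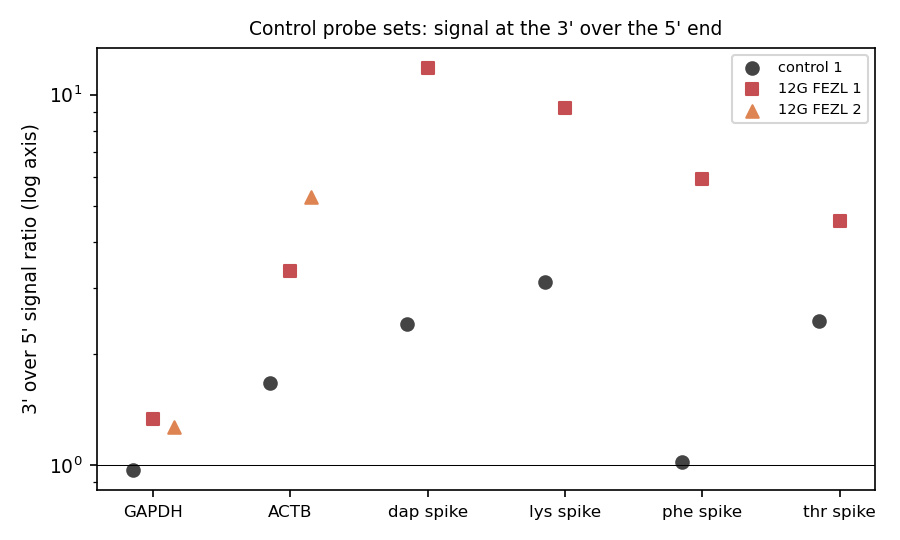
Ratio of the signal at the 3' end to that at the 5' end (log axis) for control transcripts of the cell (GAPDH, ACTB) and for added transcripts, with 1 point per array; added transcripts are left out for 12G FEZL 2, where they were at background. The ACTB ratio is 1.67 in control 1 and 3.35 and 5.29 in the transfected arrays.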

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

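All tests of explanations below were chosen after the results were seen. Flags came from the control probe sets, which the comparisons do not use. The rule covered the median signal ratio of each control family and the 3' to 5' ratios of GAPDH and ACTB, where at least 2-fold that of the control array. Ratios of added transcripts lay outside the rule. On replicate 1 they were higher too, at 11.8 against 2.40 for dap, 9.20 against 3.12 for lys, 5.92 against 1.02 for phe and 4.57 against 2.46 for thr. The hybridisation controls, added after labelling, had a median ratio to the control array of 2.43 on 12G FEZL replicate 2. The ratio of 3' to 5' signal of ACTB was 3.35 on replicate 1 and 5.29 on replicate 2, against 1.67 on the control array.

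The first pattern is that 68 probe sets were called lower and none of them is the brightest of its gene. A lower level of whole transcripts was taken to mean a fall of at least 1 in the median of the same genes' brightest probe sets. Their median was -0.38, which argues against a fall of that size for these genes as a set, not against a smaller one. Its standard error of 0.07 comes from resampling the 58 pairs and holds no spread between arrays. Of the 58, 7 lay at -1 or below. The called probe sets were picked for large falls, and no brightest one was called, so part of the gap between them may be built in. Loss of signal away from the 3' end on the transfected arrays, of which the higher ACTB ratio is a sign, may account for the pattern. The probes' positions in their transcripts are not given in the sources used here, so the brightest probe set is not known to be the one nearest the 3' end. Chosen by brightness on the control array alone, the brightest probe sets of these genes had a median of -0.44.

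The second pattern is the rise of interferon and cytokine genes. If probe position were its cause, the other probe sets of these genes should not have risen beyond random lists. Yet over 26 genes their median was 1.17, above all 10000 random lists, which treat genes as independent, and 24 of the 26 were above 0. Only probe sets past the filter on mean signal were counted. That filter favours dim probe sets that rose, so part of this rise may be built in. A labelling difference acting on whole transcripts would move all probe sets of a gene, so this comparison cannot exclude it. Whether plasmid DNA as such or 12G FEZL itself raised these genes cannot be told apart, since 0 arrays come from cells given a vector without 12G FEZL. Hybridisation day stays open too, with 1 array on each day.

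The third pattern is that many called rises are not matched by the median of the gene's other probe sets: for 37 of the 49 called single-gene probe sets with companions, the companions' median rise was under 1. Loss of signal away from the 3' end stays open as an explanation. As deposited, these probe sets exceeded the hybridisation controls by 2.59 on replicate 1 and by 0.55 on replicate 2 (log2), and the latter is too little to exclude it. Whether transcripts other than the main annotated form of the gene contribute stays open as well. The test chosen counted probe sets with no named gene. These are not among the 37, so the test cannot decide for named genes. Of the 103 probe sets called higher 31.1% had no named gene, against 11.7% of all tested (Fisher's exact test, two-sided, p = 1.22e-07; probe sets are not independent) and 5.88% of those called lower.

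The 3 arrays allow 3 choices of the lone array, too few for a share under 0.05. The real choice gave 171 probe sets past the threshold and the highest of the others gave 0, so that 1 choice reached the real count.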

How the results depend on the processing

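No paired analysis was possible because the groups share only replicate number 1. Called rises named in the report kept their direction under each alternative run per probe set. DKK1 and the dimmer called probe set of INHBA were not among those run. Alternatives that changed how a gene was represented gave counts only, without a direction for each named gene. Where values moved, the cause was not tested. The offset and the filter moved the lower calls: 32 probe sets were lower with offset 1, 140 (and 3 genes) with offset 64, and 37 (and 1 gene) with the 75th percentile filter. With no filter 0 probe sets and 0 genes passed, higher or lower; 54613 were then tested, with 3.39 prior degrees of freedom against 7.53. FEZF2 then kept differences of 8.20 (adjusted p = 0.152) and 4.76, and CXCL8 one of 3.90 (both adjusted p = 0.493). As deposited, 59 probe sets (33 genes) were higher and 159 (6 genes) lower, and 26 of the 39 genes were shared with the quantile-normalised set. Median centring gave 991 probe sets (244 higher, 747 lower) and 170 genes (104 higher, 66 lower). Without the variance trend 108 probe sets (63 higher, 45 lower) and 31 genes (31 higher) passed. The mean of a gene's probe sets left 9 genes, all 9 higher; in alternatives chosen after seeing the data, the brightest probe set on the control array left 33, all 33 higher, and requiring the other probe sets to agree left 9, all 9 higher. Probe sets at least 2-fold higher in both transfected arrays numbered 1425 with offset 1, 381 with offset 64, 514 with the 75th percentile filter, 252 as deposited and 507 with median centring, and those lower numbered 567 with offset 64, 545 with that filter, 3330 as deposited and 2226 with median centring. At 3-fold there were 264 higher and 281 lower. With either transfected array left out there were 1414 to 2079 higher and 1735 to 2221 lower.

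Lists past the camera threshold went from 9 to 0 with an estimated correlation, where p values rest on 1 degree of freedom, and to 14 as deposited. Against random lists 11 passed with both transfected arrays, and between 6 and 15 with either left out. Without replicate 1 the acute phase list had a median of 0.01, near control and below that of all tested genes (adjusted p = 0.836 against random lists). Without replicate 2 the list was higher (adjusted p = 0.000828 against random lists). With no filter the semaphorin, hypoxia and acute phase lists did not pass (adjusted p = 0.216, 0.0824 and 0.611). The interferon, NF-kB, MHC class I, cholesterol and fatty acid lists kept direction and threshold in each camera and random-list test run except that with an estimated correlation. The rotation test fry, which does not compare a list with other genes, did not pass for any of these 5 (adjusted p = 0.583 for each). TNF passed with median centring (2.30, adjusted p = 0.0227), as did CXCL8 211506_s_at (1.97, adjusted p = 0.0432). For probe sets near background, the offset set the size: SEMA5A 229427_at gave 2.40 with offset 1, 0.23 with offset 64 and 0.85 with median centring, 213169_at gave -0.71 and -0.10 with these offsets, and 205405_at gave -0.17 with offset 1 and 0.13 with median centring. FEZF2 221086_s_at gave -0.44 with offset 1, -0.053 with offset 64, -0.31 as deposited and -0.072 with median centring.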

Other observations

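Other lists outside the comparisons described held genes with higher values in both transfected arrays, none of the lists past the camera threshold with quantile-normalised values, the median filter and brightest probe sets. Sensors of foreign nucleic acid had a median of 0.44 over 12 members (camera, adjusted p = 0.0607, or 0.0424 as deposited; adjusted p = 0.778 with an estimated correlation), and 3 of them passed when adjusted over the list alone: TLR3, a receptor for double-stranded RNA (1.49 ± 0.42 SE), ZNFX1 (1.37 ± 0.40 SE) and IFIH1, the cytosolic sensor MDA5 (1.09 ± 0.33 SE). Among apoptosis regulators, TNFSF10, the death ligand TRAIL, gave 1.41 ± 0.42 (SE) and its receptor TNFRSF10B 1.30 ± 0.41 (SE), while the list's median was 0.22 over 25 members (camera, adjusted p = 0.302). Among Wnt targets, DKK1, a secreted Wnt inhibitor, was the 1 of 12 members past the threshold (3.18 ± 0.45 SE; limma, adjusted p = 0.0296). Mesenchymal genes had a median of 0.88 over the 10 tested of 22 listed, and basal breast genes one of 0.67 over 13 of 20 (camera, adjusted p = 0.117 and 0.0943). KRT14, a basal keratin, gave 2.02 ± 0.59 (SE) from a deposited control signal of 7.3, in the background range of 1.4 to 10.9. The filter on mean signal lets genes dim on the control array in more readily where they rose. These medians therefore need not hold for the untested members. Both lists passed against random lists (adjusted p = 0.00193 and 0.00709) and in camera as deposited (adjusted p = 0.00129 and 0.0134), and neither did with an estimated correlation (adjusted p = 0.778 for each). Without replicate 1 neither stood apart from random lists (adjusted p = 0.0819 and 0.232). Luminal breast genes had a median of -0.14 over 22 members (camera, adjusted p = 0.589), with the luminal keratin KRT8 at -0.82 ± 0.28 (SE).

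The brightest and the other probe sets of 1 gene gave different pictures for the stress lists, in a comparison added after seeing the data. For the unfolded protein and integrated stress response the other probe sets had a median of -0.73 over 14 genes, and the brightest probe sets of the same genes one of 0.23. For heat shock proteins these medians were -0.97 and -0.27 over 9 genes. For G2 and M phase genes they were -0.96 and -0.78 over 15 genes. The 3 probe sets for 18S ribosomal RNA had a median signal of 341.8 on the control array, 2.40 on 12G FEZL replicate 1 and 314.7 on replicate 2.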
